A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

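The samples were 10 ChIP-seq libraries from 5 lysates of Saccharomyces cerevisiae SK1 in meiosis, with groups taken from the labels. The wild-type groups at 3 h and 4 h held 2 cultures each for each antibody, and the spo11-Y135F groups at 3.5 h held 1. Per the labels' protocols, cells were fixed with 1% formaldehyde, S. pombe cells from 4.5 h of meiosis were added, and chromatin was solubilised with micrococcal nuclease (25 units/ml) and brief sonication before precipitation.

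The deposited values are coverage signal: whole-number sequencing depth at each base of each chromosome, with no header and no scaling to library size or spike-in visible in the values. BWA 0.7.12-r1039 and the build sacCer2 are named in the submitters' processing notes. The handling of duplicates, filters, fragment extension and the S. pombe build are not given in the sources used here. Since the values are depth and not counts, no count model was used. SK1 reads placed on a reference of another strain can lose depth where the strains differ, in both libraries of a lysate.

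Depth was summed per library. Mean S. cerevisiae depth was 129 to 201, and the median length of isolated fragments was 127 to 157 bp. S. pombe chromosomes I and II held at least 1552 to 15069 fragments, counted from rises in depth, so the counting error of the spike-in was 0.815% to 2.54%. The highest 1% of S. pombe bins held 27.8% to 50.1% of S. pombe depth. PCR duplicates are not independent molecules, so these errors cover counting only.

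Mean depth was taken in 12063 bins of 1 kb. Bins were kept when their H3 depth, divided by the library median and averaged over the H3 libraries, lay between 0.25 and 4, which left 11797 bins and removed 232 below and 34 above. Depth was divided by the library's mean over kept bins. Log2(relative depth + 0.05) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend), with 1 mean for each of 6 groups and 4 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale and understate changes in bins of low depth. Contrasts were H3 T11ph against H3 in wild type, 4 h against 3 h in wild type after subtraction of H3, and wild type against spo11 after subtraction of H3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The fits were tested on simulated data with 200 changed bins among 11797, 50 for each fold, and with independent noise. In the data, far more bins were called for H3 T11ph against H3 and for wild type against spo11. The recovered shares below therefore do not measure recovery in those fits. For H3 T11ph against H3, 78% of bins changed 1.5-fold and 92% of those changed 2-fold were recovered. For wild type against spo11 the shares were 4% at 1.5-fold, 50% at 2-fold, 84% at 3-fold and 76% at 4-fold.

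The spike-in scaled level of a lysate is S. cerevisiae over S. pombe depth in the H3 T11ph library divided by the same ratio in the H3 library. Both depths include mitochondrial DNA. The level was compared with exact permutation tests on log2 values, two-sided. Correlations with chromosome length used 100000 permutations. Region classes were compared by the difference of median log2 ratios within each lysate. Nucleosome-depleted windows were 150 bp windows with pooled H3 depth under 0.4 of the mean.

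Cultures are numbered in the labels, and each was sampled at both times, so the numbers pair the wild-type samples. Deviations of same-numbered samples from their group means correlated at r = 0.54 for H3 and 0.42 for H3 T11ph. The 4 wild-type lysates are therefore 2 cultures sampled at 2 times, and p-values that treat them as 4 measure the spread between lysates. The block by culture and the block by lysate were run as alternatives.

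The comparisons, the tests, the filter and the rule for named regions were fixed before the data were examined. For each contrast the rule took the 10 largest positive and 10 largest negative bins past the threshold and with the same sign in every wild-type lysate (for the mutant comparison, every wild-type lysate on the same side of spo11), with neighbouring bins merged. Alternatives covered the pseudocount (0.01 and 0.5), the bin filter, quantile normalization, spike-in scaling, 5 kb bins, both blocks, each wild-type library left out in turn, and the extent of chromosome ends. Gene coordinates in sacCer2 were not used here, and coordinates of another build were not converted. The planned parts on genes, gene lists, centromeres, transfer RNA genes, transposons and marker loci of the strains were therefore not analysed here, and regions are named by position only.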

Results

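Histone H3 phosphorylated on threonine 11 (H3 T11ph) is a mark placed during meiotic prophase by Mek1, a kinase activated at the DNA breaks that start recombination. Chromatin immunoprecipitation and sequencing measured where this mark lay in synchronous meiotic cultures of budding yeast strain SK1, which sporulates quickly and evenly. The 10 libraries came from 5 lysates, each precipitated once with an antibody against H3 T11ph and once with an antibody against all H3. Of the lysates, 4 came from 2 independent wild-type cultures sampled 3 h and 4 h after transfer to sporulation medium. The remaining lysate came from a single spo11-Y135F culture at 3.5 h. Spo11 is the enzyme that makes the meiotic breaks, and this mutant protein lacks its catalytic tyrosine. Fission yeast (Schizosaccharomyces pombe) cells in meiosis were added to every sample at 1% of the cell number as a spike-in. Mean depth over the nuclear S. cerevisiae genome was 129 in the spo11 H3 T11ph library and reached 201 in the H3 library of wild-type culture 1 at 4 h. S. pombe mean depth was far lower, from 0.0384 in the H3 T11ph library of culture 2 at 4 h to 0.333 in the H3 library of culture 1 at 4 h.

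The first comparison asked how much H3 T11ph each lysate held relative to its H3 once both were scaled to the spike-in. The level was 3.89 ± 1.62 in wild type (SD, n = 4 lysates) and 0.792 in the spo11 lysate. Each wild-type lysate lay above the mutant. Culture 1 gave 2.77 at 3 h and 2.23 at 4 h, and culture 2 gave 5.39 at 3 h and 5.16 at 4 h. On the log2 scale wild type exceeded spo11 4.57-fold, and the exact two-sided permutation test gave p = 0.2, the smallest value that 4 lysates against 1 allow. The fold was 6.40 without ribosomal DNA, mitochondrial DNA and the highest 1% of bins. The counting interval (95%) of the S. pombe fragments ran from 0.772 to 0.812 for spo11 and from 2.17 to 2.30 for the lowest wild-type lysate. These intervals cover counting error only.

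**Figure D1:**
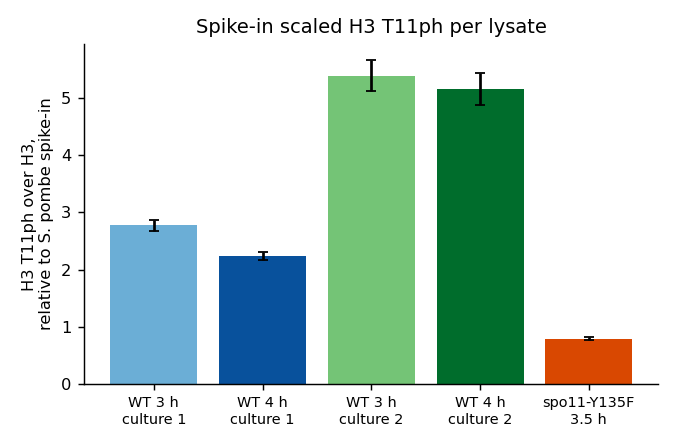
H3 T11ph over H3 relative to the S. pombe spike-in (vertical axis, ratio without unit) for each of the 5 lysates, with 95% counting intervals of the S. pombe fragments as error bars. The 4 wild-type lysates lie between 2.23 and 5.39 and the spo11 lysate at 0.792.

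The scaled level did not separate the 3 h and 4 h samples. It was 4.08 ± 1.85 at 3 h and 3.70 ± 2.07 at 4 h (SD, n = 2 cultures each), a 0.878-fold change in geometric means (exact two-sided permutation test, p = 0.667, where 0.333 is the smallest possible). That test does not pair the samples of a culture. Within culture 1 the change from 3 h to 4 h was 0.806-fold and within culture 2 it was 0.957-fold. The exact test paired by culture gave p = 0.5, the smallest possible with 2 cultures. The difference between cultures, 2.12-fold, was larger than the difference between times. Leaving out 1 lysate weights the cultures unequally, and the ratio then turned to 1.33 without culture 1 at 4 h and to 1.22 without culture 2 at 3 h.

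The second comparison asked where along the genome H3 T11ph stood above or below H3 in wild type. The strongest enrichment formed short regions on the 3 shortest chromosomes, I, III and VI, which held 8 of the 10 highest regions named by the fixed rule. Positions here are those of the sacCer2 build. Each depth is relative to its library's mean over kept bins, so these folds compare with the genome average and are not amounts of mark per histone. The highest region was chromosome III 231001 to 235000, where relative H3 T11ph depth in the leading bin was 7.00-fold of relative H3 depth (log2 2.81, SE 0.14). A neighbouring region, chromosome III 218001 to 220000, reached 6.36-fold (log2 2.67, SE 0.13). On chromosome VI, the region 199001 to 201000 reached 6.08-fold, where spo11 also stood at 3.42-fold, and the region 216001 to 218000 reached 5.82-fold. On chromosome I, 94001 to 96000 reached 5.17-fold and 79001 to 81000 reached 4.46-fold. The regions outside these chromosomes were chromosome VIII 184001 to 185000 at 4.56-fold and chromosome X 368001 to 369000 at 4.17-fold. The leading bins of the other regions also stood above H3 in spo11, and over all 10 the spo11 ratio ran from 0.53 to 1.77 (log2). The rule required the same sign in each of the 4 wild-type lysates, and the limma adjusted p of the 10 was at most 2.6e-07. That fit does not pair the libraries of a lysate. With blocking by lysate the smallest limma adjusted p over all bins was 4.9e-06.

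Of 11797 bins of 1 kb, 3002 (25.4%) were higher in H3 T11ph than in H3 and 5683 (48.2%) were lower (limma, adjusted p under 0.05). The median change of the called bins was 1.51-fold upward and 1.52-fold downward, and 573 bins were over 2-fold higher. Called bins formed 874 higher stretches with a median of 2 kb, the longest being the 37 kb from 70001 to 107000 of chromosome I. Lower bins formed 1279 stretches, the longest being the 46 kb from 32001 to 78000 of chromosome XV. The balance of higher and lower bins is set by the scaling, and the counts above are relative to the genome average. Quantile normalization called 4099 bins higher (34.7%) and 3981 lower (33.7%). Blocking by lysate, which pairs the antibodies, called 2787 higher (23.6%) and 5429 lower (46.0%). Scaling to the spike-in moved the median bin from -0.21 to 1.65 (log2) and called 10059 higher (85.3%) and 0 lower, with 10277 bins at an unadjusted limma p under 0.05 in either direction.

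The bin with the least H3 T11ph relative to H3 by the fixed rule was chromosome XII 489001 to 490000, at 0.223-fold (log2 -2.17, SE 0.22). It was followed by chromosome XV 45001 to 46000 at 0.234-fold and by the 7 kb region 303001 to 310000 of chromosome VIII at 0.324-fold. The chromosome XII bin lies close to the ribosomal DNA, at 451001 to 469000 of that chromosome. Whether the bin takes up reads from there was not tested. Each leading bin among the 10 lowest regions had more H3 coverage than the typical bin, from 1.11 to 3.19 relative to the library median. These bins were chosen for a low ratio to H3, its denominator, which favours bins of high H3. None of the 10 was on chromosome I, III or VI.

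**Figure D2:**
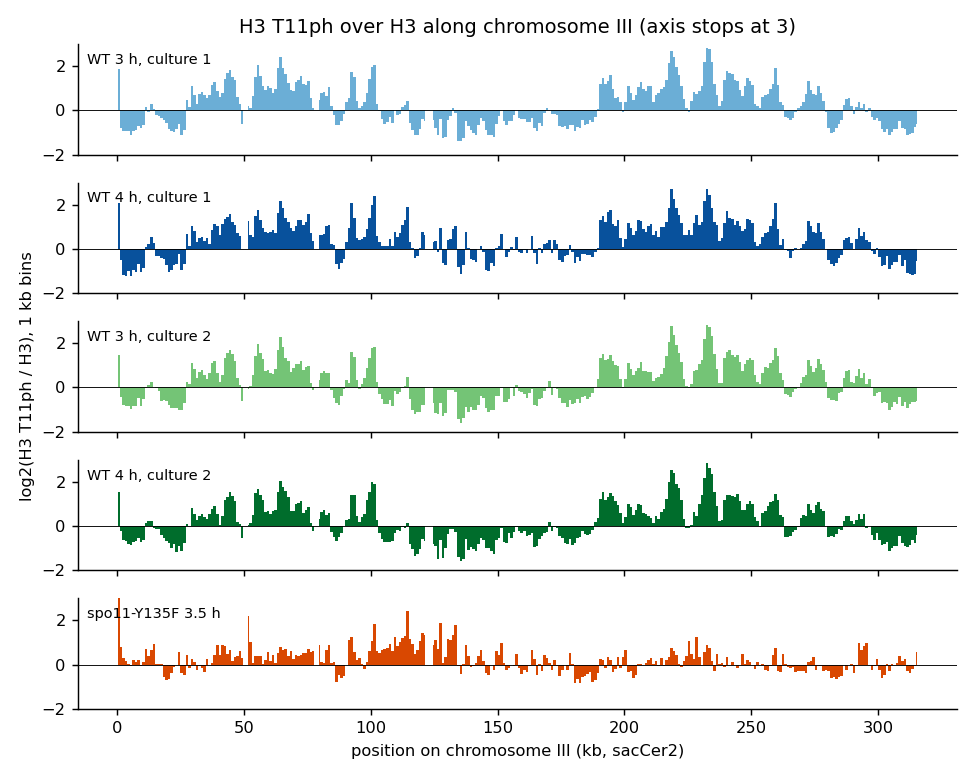
Log2 of H3 T11ph over H3 in 1 kb bins (vertical axis) along chromosome III (horizontal axis, kb, sacCer2), with 1 panel for each of the 5 lysates. The peaks at 231001 to 235000 and 218001 to 220000 stand in each wild-type panel, and the leading bin at the left chromosome end of the spo11 panel, at 6.16, runs off the axis.

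The profile was shared among wild-type lysates. Across 1 kb bins, which are not independent replicates, log2 of H3 T11ph over H3 correlated between wild-type lysates with r from 0.759 to 0.973. The 3 lower values each involved culture 1 at 4 h, and the highest joined both times of culture 2. The spo11 profile correlated with the wild-type ones at 0.110 to 0.595, and the highest of these was again with culture 1 at 4 h.

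Chromosomes differed in their average enrichment. Mean log2 of H3 T11ph over H3 was 0.41 ± 0.10 on chromosome I, 0.32 ± 0.15 on VI and 0.25 ± 0.11 on III (SD, n = 4 wild-type lysates). Chromosome X stood at 0.01 and the other chromosomes between -0.10 on XI and -0.33 on XII. Together I, III and VI exceeded the others by 0.49 ± 0.08 (1.40-fold, n = 4) in wild type and by 0.23 (1.18-fold) in spo11. The share of bins called higher was 57.7% on chromosome I and 15.7% on chromosome XII.

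The question of whether enrichment follows chromosome length was tested over 16 chromosomes. The permutations exchanged chromosomes, so their p-values do not measure the spread between lysates or cultures. The spo11 values rest on 1 lysate. In wild type, mean log2 ratio against log2 length gave Pearson r = -0.75 (permutation p = 0.00146, adjusted p = 0.00292 over 6 correlations) and Spearman rho = -0.35 (permutation p = 0.185, adjusted p = 0.222). In spo11 the values were r = -0.90 (permutation p = 4e-05, adjusted p = 0.00021) and rho = -0.86 (permutation p = 7e-05, adjusted p = 0.00021). For wild type minus spo11 they were r = -0.47 (permutation p = 0.07, adjusted p = 0.105) and rho = -0.20 (permutation p = 0.462). The r of this difference passed an unadjusted 0.05 without bins within 20 kb of ends (-0.60, permutation p = 0.0128) and, in a setting added after seeing the data, with relative H3 of at least 0.5 (-0.51, permutation p = 0.0439). Without the 3 shortest chromosomes it passed in the opposite direction (0.59, permutation p = 0.0326). Without chromosomes IV and I, the 2 farthest from the median length, r was -0.66 in wild type, -0.87 in spo11 and -0.31 for the difference. The wild-type relation rests on I, III and VI, since r was 0.16 without them (permutation p = 0.611). In spo11 r without them was -0.69 (permutation p = 0.00934) and rho -0.75 (permutation p = 0.00424).

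**Figure D3:**
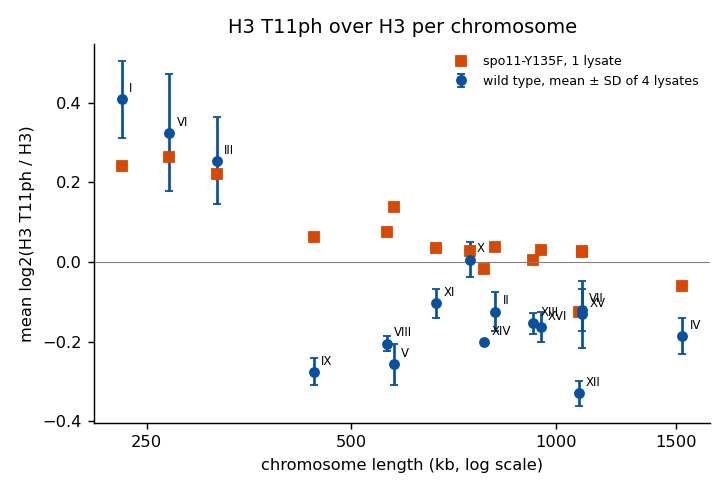
Mean log2 of H3 T11ph over H3 per chromosome (vertical axis) against chromosome length (horizontal axis, kb, log scale). Circles show wild type with the SD of 4 lysates as error bars, and squares the single spo11 lysate. Chromosomes I, VI and III lie highest in wild type, at 0.41, 0.32 and 0.25.

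Chromosome ends, the ribosomal DNA and nucleosome-depleted sites were also compared with the rest of the genome. Bins within 20 kb of a chromosome end lay at 0.665-fold of the rest in wild type (log2 -0.59 ± 0.04, SD, n = 4) and 1.13-fold above it in spo11. In the outermost 5 kb the wild-type median was -1.03 ± 0.10 and the spo11 value 0.37. The ribosomal DNA, a tandem array of rRNA genes covered by chromosome XII 451001 to 469000, stood at 0.315-fold of H3 in wild type (log2 -1.67 ± 0.24, n = 4) and at 0.821-fold in spo11. At 6708 nucleosome-depleted windows of 150 bp the ratio lay 1.41-fold above the rest in wild type (log2 0.50 ± 0.31, n = 4) and 2.12-fold above it in spo11. These windows were chosen for low H3, the denominator of the ratio, which favours a raised ratio. H3 T11ph depth at the centre of the depleted sites was itself low, between 0.192 and 0.375 of the mean in the 4 wild-type lysates and 0.383 in spo11. Culture 1 at 4 h carried much of the wild-type value, at 0.95, and the mean without it was 0.35. With 4 lysates no exact sign-flip test of these classes can reach 0.05, so their values and SD are the result.

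**Figure D4:**
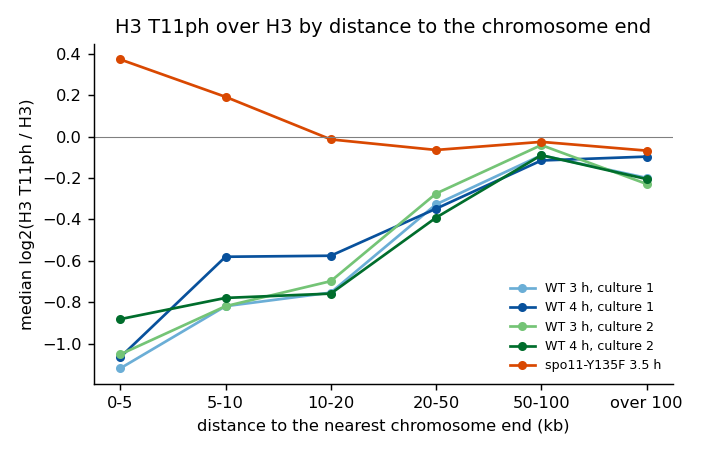
Median log2 of H3 T11ph over H3 (vertical axis) by distance to the nearest chromosome end (horizontal axis, kb), with 1 line per lysate. The wild-type lines fall toward the ends, to a mean of -1.03 in the outermost 5 kb, and the spo11 line rises to 0.37.

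No 1 kb bin passed the planned test for a change between 3 h and 4 h in wild type. Of 11797 bins, 0 were higher and 0 lower at 4 h in the limma fit, with 267 at an unadjusted p under 0.05 and a smallest adjusted p of 0.962. The block by culture also gave 0 bins, with 353 at an unadjusted p under 0.05. Simulated changes were recovered in 48% of bins at 2-fold and in 94% at 3-fold, while changes of 1.5-fold, recovered in 8%, were mostly missed. The simulated noise was independent between bins, with its spread shuffled among them, so recovery in the data may differ. Without the H3 T11ph library of culture 2 at 4 h, limma called 845 bins higher and 609 lower. The 4 h H3 T11ph group then holds culture 1 alone, assumed to vary like the other groups, so time and culture are mixed in that fit.

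The last comparison asked which parts of the wild-type profile differ from a lysate without meiotic breaks. The region most above spo11 was chromosome III 232001 to 236000, which was 4.03-fold higher in wild type (log2 2.01, SE 0.34), and chromosome III 217001 to 220000 was 3.78-fold higher (log2 1.92, SE 0.29). Chromosome X 299001 to 301000 followed at 3.74-fold, chromosome VI 215001 to 219000 at 3.64-fold, chromosome I 94001 to 97000 at 3.42-fold and chromosome II 655001 to 657000 at 3.41-fold. The other 4 of the 10 named regions, on VI, XV, X and VI, were 3.13-fold to 3.20-fold higher. In the leading bins of all 10 the spo11 ratio to H3 was between -0.07 and 0.75 (log2), and the limma adjusted p was at most 0.00324. These errors and p-values take their spread from the 2 wild-type cultures, since spo11 has 1 lysate.

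The regions most below spo11 were of another kind. The first 1000 bases of chromosome III were 21.6-fold lower in wild type (log2 -4.43, SE 0.56), although H3 T11ph stood above H3 there in wild type too, at 3.31-fold, and relative H3 coverage was 0.517. Chromosome XIV 6001 to 7000 was 6.76-fold lower, chromosome IV 1525001 to 1526000 was 6.72-fold lower and chromosome XII 5001 to 6000 was 6.66-fold lower. Of the 10 regions, 6 lay within 20 kb of a chromosome end. Most of the leading bins were poor in H3. Relative H3 coverage was at most 0.517 except on chromosome VIII 556001 to 557000, at 0.880, and on chromosome XII 1065001 to 1066000, at 1.59. The lowest was 0.288, on chromosome XV 908001 to 909000.

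Over all bins, 1850 (15.7%) were higher in wild type than in spo11 and 3050 (25.9%) were lower (limma, adjusted p under 0.05), with a median fold of 1.74 and 1.88. The mutant has 1 culture, which the fit assumes to vary like the wild-type ones. Quantile normalization called 2532 higher (21.5%) and 2142 lower (18.2%). Blocking by lysate called 1188 higher and 2249 lower. Under spike-in scaling, which moved the median bin from -0.15 to 2.05 (log2), limma called 0 bins in either direction, with 2900 at an unadjusted p under 0.05. Without the H3 T11ph library of culture 1 at 4 h the counts were 2829 and 4179, and without the H3 library of culture 2 at 3 h the lower count was 1938.

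**Figure D5:**
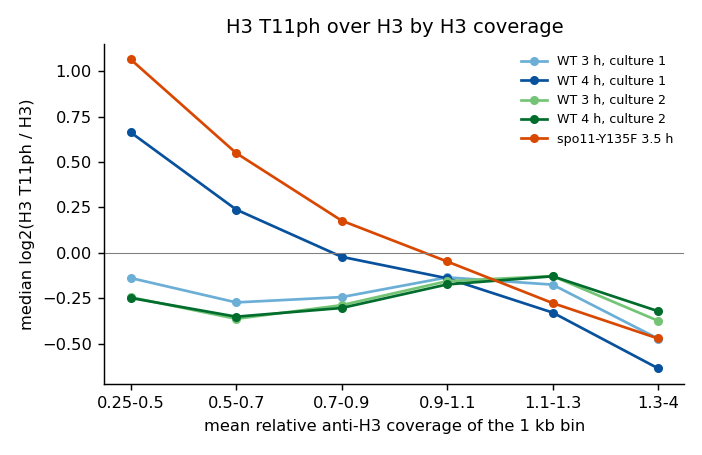
Median log2 of H3 T11ph over H3 (vertical axis) by the mean relative anti-H3 coverage of the 1 kb bin (horizontal axis, fold of the library median), with 1 line per lysate. In the bins poorest in H3 the medians are 1.06 in spo11, 0.66 in culture 1 at 4 h and between -0.25 and -0.14 in the other wild-type lysates.

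The H3 T11ph to H3 ratio moved with H3 coverage in the spo11 lysate and in culture 1 at 4 h. In the 553 bins with relative H3 under 0.5 its median log2 ratio was 1.06, and in bins over 1.3 it was -0.47. Wild type was as low in the bins over 1.3, at -0.45 ± 0.14 (SD, n = 4), and culture 1 at 4 h stood at -0.64 there. In the same poor bins the wild-type medians were -0.14 for culture 1 at 3 h, 0.66 for culture 1 at 4 h, -0.24 for culture 2 at 3 h and -0.25 for culture 2 at 4 h. Mitochondrial DNA, which carries no histone, had a depth of 2405 per 1000000 of nuclear depth in the spo11 H3 T11ph library and of 235 to 842 in the wild-type ones.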

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

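The tests in this part were chosen after the results they address were seen, except that of H3 depth in H3-poor bins, which was written down before. The first result singled out is the difference between the wild-type and spo11 profiles, a difference between groups in the limma contrast, with 1850 bins higher and 3050 lower in wild type. That contrast holds 1 mutant lysate, assumed to vary like the wild-type ones, and under spike-in scaling it called 0 bins in either direction (2900 at an unadjusted p under 0.05, smallest limma adjusted p 0.192). The second is mitochondrial DNA, which carries no histone H3 and lies outside the 1 kb bins, although the spike-in scaled level includes it. Its depth per 1000000 of nuclear depth was 688 in the H3 T11ph library of culture 1 at 3 h, 842 in that of culture 1 at 4 h, 584 in that of culture 2 at 3 h and 2405 in that of spo11. Each exceeds the highest H3 library, at 282, while the H3 T11ph library of culture 2 at 4 h, at 235, does not.

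In the spo11 lysate H3 T11ph over H3 rises where H3 is low, and so it does, less steeply at that end, in culture 1 at 4 h. Lower H3 in those bins of the spo11 H3 library is argued against, since the median log2 of spo11 over wild-type H3 there was -0.0100. Nonspecific recovery of DNA without H3 goes with the spo11 data: S. cerevisiae mitochondrial depth in the spo11 H3 T11ph library was 2.85 times the highest wild-type one, while the spo11 H3 library had the lowest of the H3 libraries, at 66.9. In wild type it is less clear. The highest such depth was in culture 1 at 4 h, at 842, against 688 in culture 1 at 3 h. The H3-poor bins were raised only in the former of these (median log2 0.66 against -0.14). S. pombe mitochondrial over total S. pombe depth in the spo11 H3 T11ph library, at 3.92, lay between those of culture 1, at 4.91 and 5.34, and those of culture 2, at most 1.62. With little specific target in the mutant such background may fill a larger share of the library, so the 3050 lower bins may partly hold background, while a real mark at H3-poor sites in spo11 stays open and untested.

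Chromosomes I, III and VI carry more H3 T11ph over H3 in wild type. Lower H3 depth on them is argued against, since their mean log2 H3 differed from the others by 0.00159 against an excess of 0.49. Distance from the ends is argued against as the whole cause, since the excess was 0.600 against bins of the other chromosomes at the same distance, although it was 0.98 ± 0.12 at 50 to 100 kb and 0.14 ± 0.16 beyond 100 kb (SD, n = 4). Carry-over of wild-type DNA is argued against as the whole cause of the smaller excess in spo11: over the 6278 bins with relative H3 of 0.8 to 1.2, regression on the wild-type ratio left 0.0789 of an excess of 0.159 in the linear ratio (exact permutation p = 0.0143 over 560 choices of 3 chromosomes), and a carried-over part stays open. The genotype, with 1 mutant culture, stays open and untested.

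The spike-in scaled level of culture 2 is above that of culture 1. Counting error is argued against, since the lowest counting bound of culture 2 was 1.70 times the highest of culture 1. Reads of rRNA genes assigned to S. pombe are argued against, since the fold between cultures was 2.84 without rDNA and the highest 1% of bins, against 2.12 with them. Nonspecific S. pombe DNA in the culture 1 H3 T11ph libraries cannot be told apart: S. pombe mitochondrial over total S. pombe depth was higher in culture 1 with both antibodies (at least 4.91 against at most 1.62 for H3 T11ph, at least 0.134 against at most 0.0454 for H3), and the lowest H3 T11ph value over H3 of culture 1 was 0.514 of the highest of culture 2, but the H3 values rest on an estimated 1.04 to 9.01 fragments. A true difference in the mark between cultures stays open and untested.

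For H3 T11ph against H3, of 35 splits of the 8 wild-type libraries into 4 and 4, 1 gave as many bins, the real one with 8686 in a fit of 2 groups, and the highest other gave 0. The libraries are paired by lysate, and only 8 of the splits part the antibodies of every lysate, which is too few for a share under 0.05: the real one gave 8686 and the highest other 0. Splits that mix the antibodies place the difference between them in the residual spread, which favours a count of 0, so the 35 splits do not decide on chance.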

How the results depend on the processing

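The settings without both libraries of culture 1 at 4 h, with relative H3 of at least 0.5, and more than 50 kb from an end were chosen after seeing the data. Of 156 alternative values, 137 counted as unchanged by the rule for their kind. Correlations and spike-in ratios had to keep their direction and their side of the threshold. Region differences had to move by less than the spread between lysates, and shares of bins to change by under about 1.5 times. Shares for 4 h against 3 h that stayed at 0 are among the 137. The cause of the changes in the other values was not tested unless given. Spike-in scaling gave 85.3% higher and 0% lower for H3 T11ph against H3, and 0% in both directions for wild type against spo11 although the median bin rose to 2.05 (log2). The scale factor of the H3 T11ph libraries differed between cultures 1 and 2, at 1639 and 3236 at 3 h and at 1291 and 3962 at 4 h. Spike-in scaling puts this difference into the spread within groups in every bin, which works against calls. Whether it accounts for all of the lost calls was not tested. Blocking by lysate gave 10.1% higher for wild type against spo11, and leaving out both libraries of culture 1 at 4 h gave 25.1% higher. The replicate block by culture gave 3040 higher and 5742 lower bins for H3 T11ph against H3, 0 for 4 h against 3 h, and 1998 and 3080 for wild type against spo11, and moved no count by over 1.5 times. Leaving out 1 library gave 22.6% to 27.9% higher and 43.1% to 51.3% lower for H3 T11ph against H3, 0% to 7.16% higher and 0% to 5.16% lower for 4 h against 3 h, and 11.2% to 24.0% higher and 16.4% to 35.4% lower for wild type against spo11. The spike-in ratio of wild type to spo11 ran from 4.01 to 5.37 and that of 4 h to 3 h from 0.578 to 1.33 (1.22 without culture 2 at 3 h), since leaving out 1 lysate unbalances the cultures. Without the 3 shortest chromosomes the length correlation turned to 0.16 in wild type and to 0.59 for wild type minus spo11, which became -0.60 without bins within 20 kb of ends and -0.51 with relative H3 of at least 0.5. The end difference was -0.67 within 10 kb and -0.35 within 50 kb, and the excess of I, III and VI was 0.61 more than 50 kb from an end. The alternatives planned for genes, gene lists and centromeres were not run. The sparsest library held at least 1552 S. pombe fragments on chromosomes I and II, a counting error of 2.54%, which covers counting only. The 2.12-fold difference in scaled level between cultures was larger than counting error.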

Other observations

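The test of spacing and the pile-ups in this part were chosen after the profiles were seen. The 50 kb window most enriched in wild type was chromosome III 200001 to 250000, at 2.20-fold (log2 1.13 ± 0.07, SD, n = 4), followed by chromosome I 50001 to 100000 at 1.86-fold and chromosome VI 200001 to 250000 at 1.85-fold. The lowest was chromosome XV 350001 to 400000, at 0.543-fold, and the spo11 values of these 4 windows were 0.19, 0.14, 0.35 and 0.11 (log2).

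The spo11 H3 T11ph library held narrow pile-ups at the tips of chromosomes. Outside the ribosomal DNA and its surroundings, 14 stretches exceeded 20 times the mean depth in it, against 0 in the 4 wild-type H3 T11ph libraries and 2 to 6 in the H3 libraries. The threshold lies just above the wild-type H3 T11ph maxima outside chromosome XII, which were 14.4 to 19.8, and 2 of the 14 stretches, on chromosome XVI, 645556 to 645632 and 645634 to 645637, adjoin. Chromosome XV 31010 to 31203 was as high in spo11 H3 (31.0) as in spo11 H3 T11ph (29.9). Of these, 5 lay within 50 bp of a chromosome end and 9 within 20 kb. The highest was chromosome XIV 784059 to 784318, with a mean depth of 119.8 times the library mean in spo11 H3 T11ph against 1.11 in spo11 H3. The wild-type H3 T11ph libraries stood at 5.08, 12.5, 5.70 and 4.75 there, in the order culture 1 at 3 h, culture 1 at 4 h, culture 2 at 3 h and culture 2 at 4 h. Chromosome III 21 to 356 followed with 89.1 in spo11 H3 T11ph against 0.659 in spo11 H3.

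A hypothesis was that enriched regions in wild type have a preferred spacing of 10 to 15 kb, since the autocorrelation of the profile was 0.199 at 8 kb and 0.216 at 11 kb. The test gave a negative result: the mean autocorrelation at 10 to 15 kb minus that at 6 to 8 kb was 0.0107 over 16 chromosomes, positive on 10 of them (sign-flip permutation p = 0.494). In the single spo11 lysate the same difference was -0.0312, positive on 4 of 16 chromosomes.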
